A study of Bos taurus with 24 samples.

How the data were processed

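RNA sequencing libraries were made from liver and mammary gland of 12 lactating dairy cows, 6 fed a diet based on alfalfa hay and 6 fed a diet based on corn stover for 12 weeks before slaughter, giving 24 libraries. Per the labels' protocols, total RNA was extracted from ground frozen tissue and libraries followed standard Illumina protocols. Backfat, which the protocol also mentions, was not analysed here. For each cow the labels gave milk yield, dry matter intake, parity and days in milk. These values were identical for the liver and the mammary library of the same diet and number in all 12 cows, so such libraries were taken as one animal. Each diet held 1 cow of parity 2, and the other cows were of parity 3.

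The deposited files hold raw read counts per gene, one file per library, with the same 24616 Ensembl bovine gene identifiers in each. Per the submitters' processing notes, TopHat2 2.0.9, SAMtools 1.1, HTSeq 0.6.1 and the genome build UMD3.1 were used by the authors; their order, the annotation release, the strand setting and the read filters are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies may therefore be split or lost in ways that cannot be traced. The counts are whole numbers, and no file holds a summary line for unassigned reads. No libraries held identical counts. Total counts per library ran from 22579051 to 37954234, and genes at a few reads per library carry the counting error of those reads.

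The files do not pair the identifiers with gene names, and 0 of the 24616 identifiers matched the gene table used here. The 44 planned gene lists, with their tests and alternatives, could therefore not be applied, nor could the rule for named genes beyond its clause for genes without a symbol, which names the gene with the smallest p of each comparison. Further identifiers were chosen after their values were seen. They are the 2 with the smallest p in each direction for each diet comparison, and the 1 with the smallest p in each direction for the tissue and interaction comparisons. No genomic position is given for them, because no annotation of the build was used here.

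Diet was tested within each tissue (12 libraries, corn stover minus alfalfa hay) with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, a trimmed mean of ratios between libraries, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold threshold. The standard error of a log2 change was taken as its size divided by the square root of its F statistic. The difference between the tissues, and the difference of the diet effect between the tissues (interaction), were tested over all 24 libraries with 4 group means. Levels are given as normalised CPM, the count relative to the product of library total and TMM factor, scaled within a tissue, as mean ± SD. Principal components were computed within each tissue from log2 CPM. Cow measurements were compared by exact permutation of the diets over the 12 cows, two-sided, with Benjamini-Hochberg adjustment over 4 measures.

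Added after the identifiers could not be matched to names, 3 groups of genes were made from the tissue comparison: liver-enriched and mammary-enriched genes (log2 difference of at least 3 and past the threshold) and shared genes (log2 difference under 1). Their diet changes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 3 groups of a tissue. The groups come from the same libraries as the diet tests. Reads of the other tissue were measured on genes with a median of at least 1000 CPM in their own tissue and at least 1000 times their median in the other: 11 mammary-type and 60 liver-type genes. The summed CPM of these genes, per library total without TMM scaling, in a library of the other tissue was expressed in ppm of their summed median in their own tissue. Intervals for read counts would cover counting error only, since no molecular identifiers are named in the sources used here.

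Fixed alternatives were RLE size factors, no filter, a filter at 1 CPM in 6 libraries, DESeq2 1.42.0, limma voom, days in milk as a covariate, parity 3 cows only, all 24 libraries in one fit, each library or cow left out, and the replicate number or the cow as a block. Replicate numbers are shared by the diets but name different cows. Across tissues the pairing by cow comes from the labels, and the deviations of a cow's liver and mammary libraries correlated at -0.16 to 0.33. All tools were tested on simulated data with the means, library sizes and gene spreads of each tissue and 200 changed genes. In the simulated liver comparison of 12929 genes, edgeR recovered 41% of 2-fold and 88% of 4-fold changes. In the simulated mammary comparison of 12027 genes it recovered 36% of 2-fold and 89% of 4-fold changes.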

Results

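The study compared the liver and the lactating mammary gland of cows fed a diet based on corn stover, the stalks and leaves left after the grain harvest, with those of cows fed a diet based on alfalfa hay, a legume forage. RNA sequencing gave 6 libraries per tissue and diet, from 6 cows per diet that each gave both tissues. Library totals ran from 23595586 to 29574105 counts in liver on alfalfa hay and from 26125472 to 32563876 in liver on corn stover. In mammary gland they ran from 22579051 to 37954234 on alfalfa hay and from 23299391 to 30209312 on corn stover. The mammary transcriptome was concentrated in few genes. The 10 most abundant genes took 74.4% ± 4.10 of reads in mammary gland and 29.5% ± 3.44 in liver (SD, n = 12 each), and the single most abundant gene took 32.8% ± 3.60 and 11.5% ± 3.33. Reads were found for 15001 ± 399 genes in mammary gland and 15487 ± 314 genes in liver.

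The first comparison asked how the diets differed in milk output. Cows on corn stover gave less milk than cows on alfalfa hay, at 20.4 ± 2.03 against 26.3 ± 2.66 kg per day (SD, n = 6 each), a difference of 5.93 kg per day or 22.5% (exact permutation test, two-sided, p = 0.00433, adjusted over 4 measures 0.00866). Yield in 5 of the 6 corn stover cows lay below the lowest yield on alfalfa hay, which was 23.3 kg per day. Milk per kg of dry matter eaten was 1.13 ± 0.113 kg on corn stover and 1.44 ± 0.149 kg on alfalfa hay. All 6 corn stover cows lay below all alfalfa hay cows in this measure, and the exact permutation p of 0.00216 (adjusted 0.00866) is the smallest that 924 assignments allow. Dry matter intake was 18.1 ± 1.22 kg per day on corn stover and 18.3 ± 0.387 kg per day on alfalfa hay, a difference smaller than the spread between cows (exact permutation p = 0.812). Its sign turned without corn stover cow 4, to 0.283 kg per day more on corn stover. Days in milk averaged 248 ± 10.2 on corn stover and 239 ± 6.44 on alfalfa hay (exact permutation p = 0.134). Without corn stover cow 6, which was at 228 days, the difference was 12.3 days (exact permutation p = 0.0130).

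**Figure D1:**
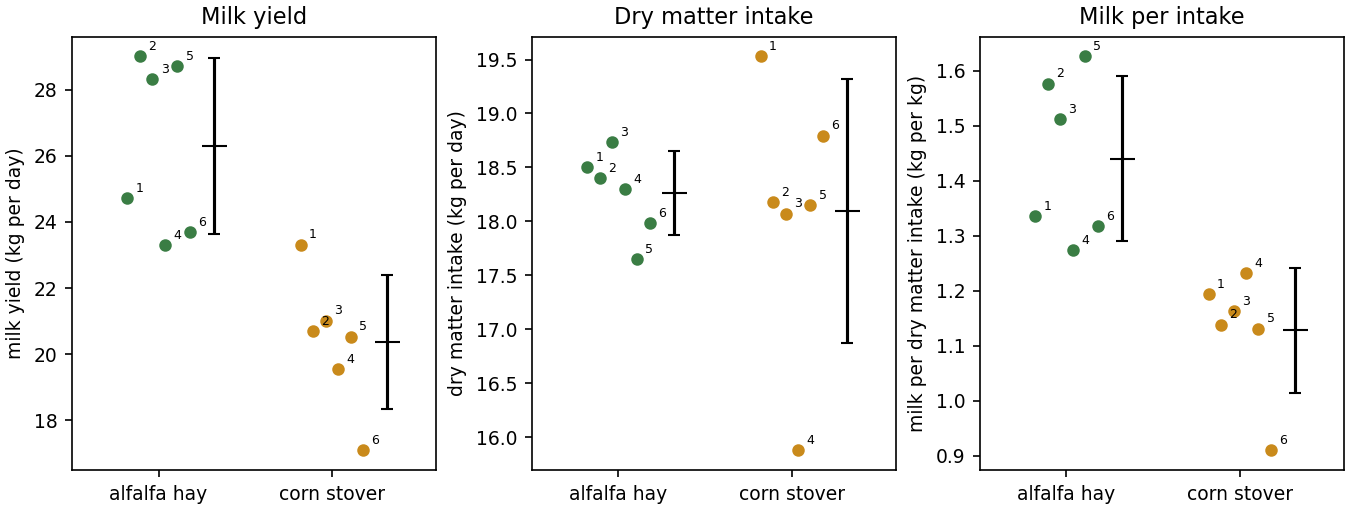
Milk yield and dry matter intake (kg per day) and milk per kg of intake for each of the 12 cows by diet; numbers are the cow numbers, and the bars at the side give the mean and SD (n = 6). Milk yield and milk per intake lay lower on corn stover, while intake overlapped.

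The tissue comparison served as a check that the labels set the tissues apart and as a frame for the diet comparisons. Without gene names no known tissue marker could be used. An exchange of the tissue labels in all cows would leave the count of genes the same. Of 13760 genes tested, 4609 were higher and 4774 lower in mammary gland than in liver (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), which is 68.2% of the genes. With the cow as a block the count was 9157 in place of 9383. ENSBTAG00000006738 had the smallest p and was mammary-enriched, at 75.9 ± 6.99 CPM in mammary gland on alfalfa hay and 51.0 ± 8.58 CPM on corn stover, against 0.034 ± 0.030 and 0.029 ± 0.041 CPM in liver (SD, n = 6; edgeR adjusted p = 3.38e-21). ENSBTAG00000008936 was liver-enriched, at 207 ± 27.4 CPM on alfalfa hay and 249 ± 56.4 CPM on corn stover in liver, against 0.019 ± 0.021 and 0.083 ± 0.068 CPM in mammary gland (edgeR adjusted p = 3.40e-21). At limits set after the data were examined, 1205 genes were liver-enriched, 902 were mammary-enriched and 7849 were shared between the tissues.

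The liver comparison asked which hepatic genes differed between the diets. No gene of 12929 tested passed the threshold (edgeR quasi-likelihood test, smallest adjusted p = 0.806). At an unadjusted p below 0.05 there were 354 genes, where chance alone would give 646. This count was 565 without corn stover replicate 1 and 754 in parity 3 cows alone. Limma voom also called 0 genes while DESeq2 called 3, a count that ran from 2 without alfalfa hay replicate 3 to 10 without alfalfa hay replicate 5. Diet did not separate the liver libraries on the first 2 principal components, which held 28.8% and 16.5% of the variance. Replicate 1 of each diet stood apart on the first component, and without these 2 libraries the count stayed at 0. Fitted changes were small, with a median size of 0.16 and a median standard error of 0.26 on the log2 scale, and 218 genes had fitted changes of more than 2-fold. In a simulation with the spread of these libraries and 200 changed genes, 88% of 4-fold changes but 41% of 2-fold changes were recovered. A 2-fold change in a single gene was thus often not detectable. The simulation drew genes independently, without structure shared between genes such as replicate 1 standing apart. With fewer changed genes the adjusted threshold is also harder to reach. Recovery in the real libraries may therefore be lower, for 4-fold changes too.

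ENSBTAG00000046768, a liver-enriched gene, had the smallest p in liver. It was at 355 ± 352 CPM on corn stover and 36.5 ± 14.96 CPM on alfalfa hay (SD, n = 6), a log2 difference of 3.28 ± 0.63 (SE; edgeR adjusted p = 0.806), and 5 of the 6 corn stover libraries exceeded every alfalfa hay library. DESeq2 called this difference (adjusted p = 0.00273), as did the fit over all 24 libraries (edgeR adjusted p = 0.0408), and over the settings tried the adjusted p ranged from 0.00273 to 0.9999. ENSBTAG00000017450, a gene shared between the tissues, was at 15.9 ± 2.83 CPM on corn stover and 8.26 ± 2.53 CPM on alfalfa hay, a log2 difference of 0.94 ± 0.22 (SE; edgeR adjusted p = 0.99999), with 5 of 6 corn stover libraries above all alfalfa hay libraries. Lower fitted values on corn stover were led by ENSBTAG00000005005 and ENSBTAG00000002555. ENSBTAG00000005005 was at 0.52 ± 0.78 CPM on corn stover and 17.8 ± 13.5 CPM on alfalfa hay in liver, and it is mammary-enriched and abundant in mammary gland, at 94289 ± 28833 and 93255 ± 30567 CPM. Its log2 difference in liver was -5.15 ± 1.07 (SE; edgeR adjusted p = 0.806). ENSBTAG00000002555, which is liver-enriched, was at 2.20 ± 1.26 CPM on corn stover and 10.8 ± 5.98 CPM on alfalfa hay, a log2 difference of -2.28 ± 0.48 (SE; edgeR adjusted p = 0.806, DESeq2 adjusted p = 0.00288, range over the settings 0.00288 to 0.9999). For both of these genes alfalfa hay replicate 6 lay at the corn stover level, at 0.22 and 1.77 CPM, and without the other 5 alfalfa hay libraries the fitted log2 differences, which then rest on this 1 library, turned to 1.23 and 0.32.

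For the liver-enriched genes as a group, the difference between the diets in liver did not pass the threshold. Of 1205 tested, 677 had higher and 528 lower fitted values on corn stover, with a median log2 difference of 0.03 (camera, adjusted p = 0.285; adjusted p = 0.861 with an estimated correlation), and 0 passed the threshold, both over all genes and adjusted over the list alone. Without alfalfa hay replicates 1 to 5, the median was 0.36, but this sets a single alfalfa hay library against 6 corn stover libraries, takes its spread from the corn stover group alone and cannot test diet. The shared genes had a median of -0.01 (camera, adjusted p = 0.285). The 376 mammary-enriched genes tested in liver had a median of 0.03 and a mean of -0.04 (camera, adjusted p = 0.914).

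The mammary comparison asked which genes of the milk-producing tissue differed between the diets. No gene of 12027 tested passed the threshold (edgeR quasi-likelihood test, smallest adjusted p = 0.165), and limma voom called 0 genes, whereas DESeq2 called 42, of which 34 were higher and 8 lower on corn stover. The DESeq2 count ran from 26 without alfalfa hay replicate 3 to 84 without alfalfa hay replicate 4. At an unadjusted p below 0.05 there were 784 genes, where chance alone would give 601. In 23 genes all 6 corn stover libraries exceeded all alfalfa hay libraries, and in 19 genes all lay below. This is 0.349% of the genes, where chance gives 0.216% on average, and the spread of this share over other splits was not computed. In liver 8 of 12929 genes separated the diets in this way, which is 0.0619%. In simulated mammary data, 24 of 169 DESeq2 calls and 7 of 132 edgeR calls were genes that had not been changed. In the same data DESeq2 recovered 51% of 2-fold and 94% of 4-fold changes, and edgeR 36% and 89%. The simulated counts were a single draw of independent genes, with spreads estimated by edgeR. They therefore cannot decide which tool's calls hold in the real libraries. The first component, with 21.8% of the variance, set corn stover replicate 6 apart and did not separate the diets.

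ENSBTAG00000037558 had the smallest p in mammary gland, at 4.20 ± 1.39 CPM on corn stover and 1.23 ± 0.392 CPM on alfalfa hay (SD, n = 6), a log2 difference of 1.76 ± 0.30 (SE; edgeR adjusted p = 0.165, DESeq2 adjusted p = 7.34e-05, range over the settings 7.34e-05 to 0.463). ENSBTAG00000001292 was an abundant mammary-enriched gene, at 1910 ± 443 CPM on corn stover and 598 ± 276 CPM on alfalfa hay, a log2 difference of 1.68 ± 0.30 (SE; edgeR adjusted p = 0.165, DESeq2 adjusted p = 3.91e-05, range over the settings 3.91e-05 to 0.411). In liver the same gene was at 8.43 ± 3.01 and 6.48 ± 5.66 CPM. ENSBTAG00000009468 was at 18.4 ± 3.50 CPM on corn stover and 50.04 ± 26.2 CPM on alfalfa hay, a log2 difference of -1.45 ± 0.28 (SE; edgeR adjusted p = 0.183, DESeq2 adjusted p = 0.00148, range over the settings 0.00148 to 0.542). ENSBTAG00000005745 was at 10.2 ± 3.61 CPM on corn stover and 27.1 ± 11.05 CPM on alfalfa hay, a log2 difference of -1.40 ± 0.30 (SE; edgeR adjusted p = 0.270, DESeq2 adjusted p = 0.00598, range over the settings 0.00598 to 0.487). In each of these 4 genes, which are all mammary-enriched, the 6 corn stover libraries lay wholly to one side of the 6 alfalfa hay libraries.

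**Figure D2:**
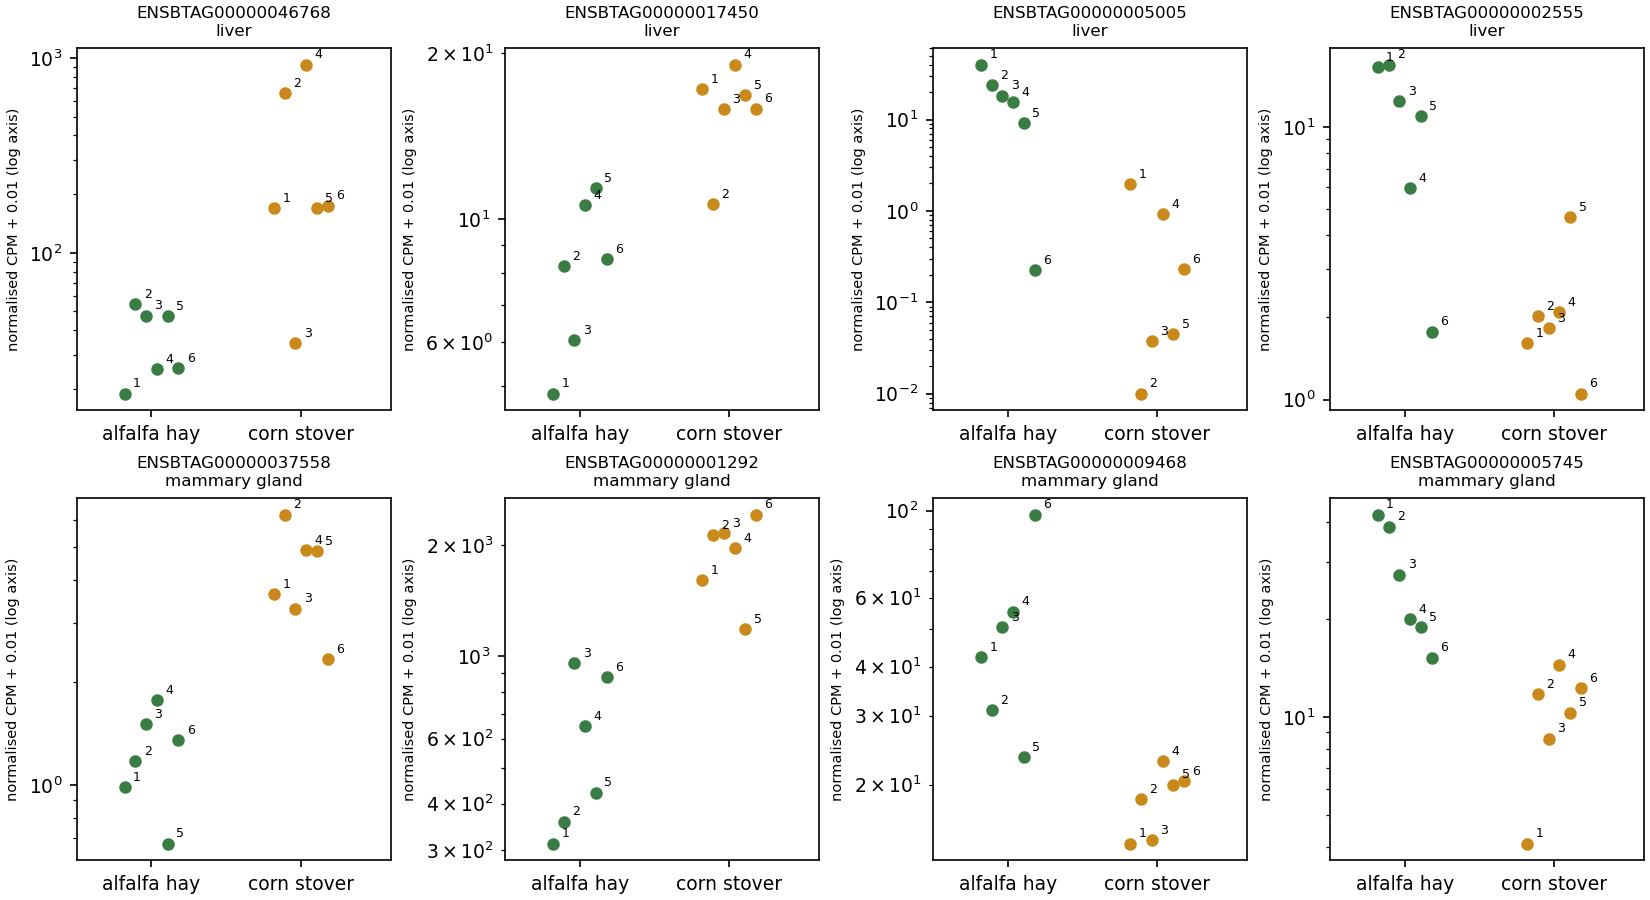
Normalised CPM (plus 0.01, log axis) in each library, for the 2 genes with the smallest p in each direction of the diet comparison in each tissue; points are libraries numbered by replicate. The 4 mammary genes separated the diets in all 12 libraries, and in ENSBTAG00000005005 and ENSBTAG00000002555 alfalfa hay replicate 6 lay with the corn stover livers.

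For the mammary-enriched genes as a group, the difference between the diets in mammary gland did not pass the threshold. Of 891 tested, 391 had higher and 500 lower fitted values on corn stover, with a median log2 difference of -0.06 (camera, adjusted p = 0.201). None passed the threshold over all genes, and 6 passed when adjusted over the list alone. For the liver-enriched genes that could be tested in mammary gland, the camera test at the preset correlation passed the threshold. It also passed with RLE size factors, while 2 other settings of camera and the fry test did not. Of 453 tested, 296 had higher and 157 lower fitted values, with a median log2 difference of 0.17 (camera, adjusted p = 2.35e-06), and 0 passed the threshold singly, over all genes or over the list alone. The call was lost with an estimated correlation (adjusted p = 0.0569). The fry test, which sets the group against no change and not against other genes, gave an adjusted p of 0.0680. The camera call was also lost without the 3 corn stover libraries that held most liver-type reads, where the median was 0.08 (camera, adjusted p = 0.0930). Of 100 splits of the 12 mammary libraries, the real one included, 15 gave a median at least as large in size. The 7357 shared genes had a median of -0.0026 (camera, adjusted p = 0.693).

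Reads typical of the other tissue were present at low levels and differed between libraries. In liver, 11 mammary-type genes stood at 147 to 296 ppm of their mammary level in alfalfa hay replicates 1 to 5, at 5.35 ppm in alfalfa hay replicate 6 and at 1.45 to 38.9 ppm in the corn stover libraries (exact permutation test on log2 values by diet, two-sided, p = 0.0130). In mammary gland, 60 liver-type genes stood at 70.8 to 400.05 ppm of their liver level on alfalfa hay and at 204 to 1976 ppm on corn stover (exact permutation p = 0.00649). Corn stover replicates 2, 3 and 4 were highest, at 1099, 1976 and 1089 ppm. Alfalfa hay livers 1 to 5 were also the 5 libraries whose count column carries the letter of the tissue in its header, unlike the 7 other livers. With this header kind as a batch term, diet rests on 1 alfalfa hay library, and 0 genes passed in liver.

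**Figure D3:**
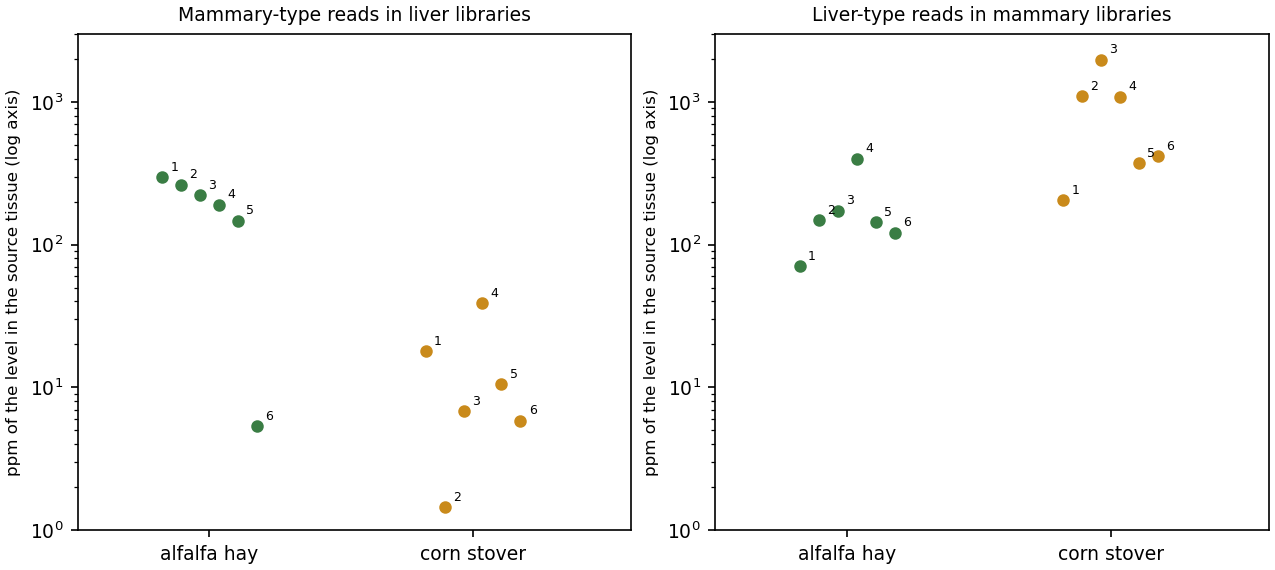
Level of mammary-type genes in liver libraries and of liver-type genes in mammary libraries, in ppm of the level in the source tissue (log axis); points are libraries numbered by replicate. In liver 5 alfalfa hay libraries stood above 147 ppm, and in mammary gland corn stover replicates 2 to 4 were highest.

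The interaction asked whether the diet effect differed between the tissues. No gene of 13760 tested passed the threshold (edgeR quasi-likelihood test, smallest adjusted p = 0.151), with 700 genes at an unadjusted p below 0.05 where chance gives 688. This fit has no term for the cow, although each cow gave both tissues. With the cow as a block, 0 genes passed and 498 were at an unadjusted p below 0.05. Without the block and without each cow in turn, this count ran from 535 to 1208, the highest without corn stover cow 1. Limma voom called 0 genes and DESeq2 called 74. ENSBTAG00000013070 had the smallest p. In liver it stood at 0.21 ± 0.13 CPM on corn stover and 1.11 ± 0.64 CPM on alfalfa hay, with 6 of 6 corn stover libraries below all alfalfa hay libraries. These are levels of few reads, 2 to 12 in the corn stover livers and 8 in alfalfa hay replicate 1. The full separation thus depends on the scaling of alfalfa hay replicate 1, whose TMM factor was 0.700. In mammary gland this gene stood at 2.32 ± 0.71 and 1.39 ± 0.47 CPM, with 4 of 6 above (log2 interaction 3.095 ± 0.57, SE; edgeR adjusted p = 0.151). With the cow as a block its log2 interaction was 3.01 (edgeR adjusted p = 0.949). In the opposite direction ENSBTAG00000046768 had a log2 interaction of -5.03 ± 1.25 (SE; edgeR adjusted p = 0.356, and 0.949 with the cow as a block). It stood at 0.046 ± 0.049 CPM on corn stover and 0.158 ± 0.131 CPM on alfalfa hay in mammary gland. Liver-enriched genes made up 51 of the 100 genes with the smallest interaction p, against 8.76% of all genes tested, and in 49 of the 51 the fitted diet change was more positive in mammary gland than in liver. Among all liver-enriched genes this held for 754 of 1205. Of these 1205 genes, 453 passed the expression filter in the mammary libraries alone. For the others the mammary side of the interaction rests on few reads. Mammary-enriched genes made up 21 of the 100, against 902 of the 13760 tested. None of these shares was tested for enrichment. Liver-type reads were also higher in the corn stover mammary libraries (exact permutation p = 0.00649).

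**Figure D4:**
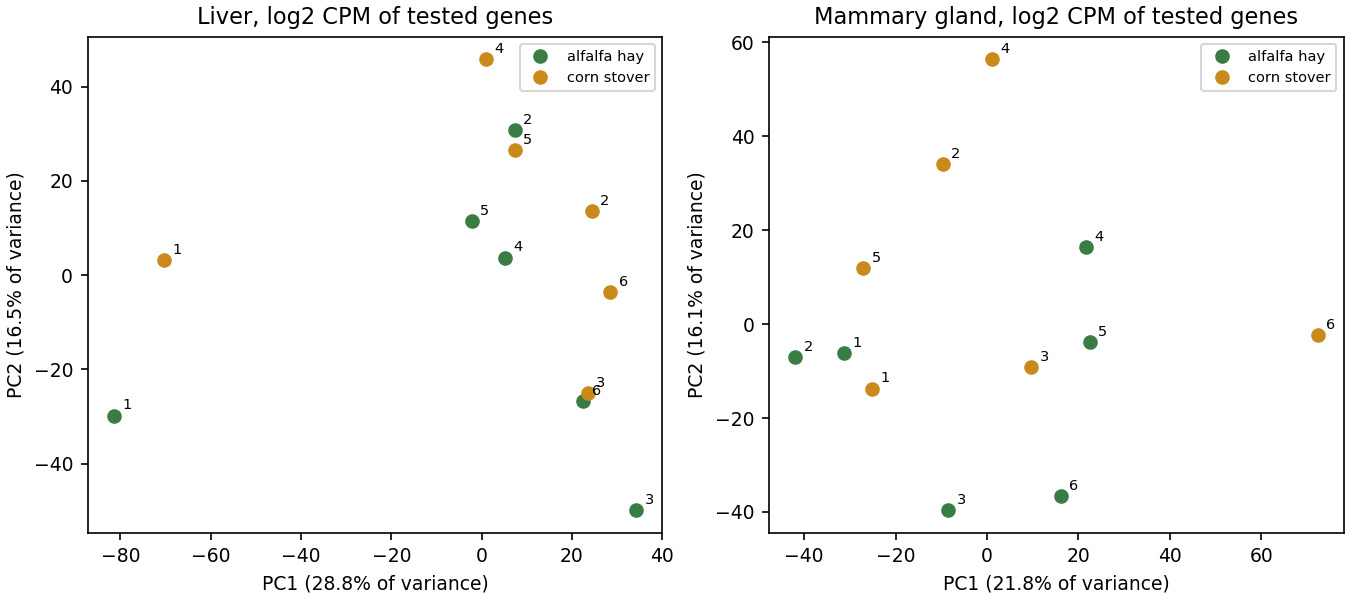
First and second principal components of log2 CPM in liver and mammary gland; each point is a library, numbered by replicate and coloured by diet. The diets overlapped in both tissues, and replicate 1 of each diet stood apart in liver.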

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

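The tests on reads of the other tissue below were chosen only after the levels were seen. Among 58 groups of 6 values checked for a sample far from the others, 12 held one, where chance would give about 2.9. In liver, replicate 1 stood apart in both diets. Its TMM scaling factor was 0.700 on alfalfa hay and 0.777 on corn stover, while the other livers ranged from 0.983 to 1.17. Genes with a read numbered 14786 on alfalfa hay and 15022 on corn stover in these libraries, and the 10 most abundant genes took 36.1% and 35.9% of their reads; within its diet only the corn stover library stood far from the others in these measures. In mammary gland, alfalfa hay replicate 4 was the deepest library at 37954234 counts and held the most liver-type reads of its group, 400.05 ppm. Corn stover replicate 1 of mammary gland had 64.6% of reads in its 10 most abundant genes and a scaling factor of 1.38. ENSBTAG00000002555 was at 4.67 CPM in liver corn stover replicate 5, against 1.04 to 2.08 CPM in the others. ENSBTAG00000006738, a mammary-enriched gene, was at 0.104 CPM in liver corn stover replicate 5, a level of a few reads. Corn stover cow 6 gave 0.909 kg of milk per kg of intake and was at 228 days in milk, both lowest in its group.

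Mammary-type reads in the 5 alfalfa hay livers lay close to the proportions of the mammary gland. For the 7 most abundant mammary-type genes the excess over the other livers was 148 to 221 ppm of the mammary level, so the highest share was 1.49 times the lowest, as carry-over of mammary RNA or reads may give. The split also followed the kind of column header, 5 files with the tissue letter against 7 without (exact permutation p = 0.00126), so a processing batch is a candidate source. Diet stays open, since all 5 libraries are alfalfa hay and the one alfalfa hay liver outside them, at 5.35 ppm, is a single library. A test of all genes by header kind (edgeR, adjusted p below 0.05) called 3 genes, ENSBTAG00000002555 and 2 mammary-enriched genes, of which 1 was ENSBTAG00000005005 (adjusted p = 0.0236 each). ENSBTAG00000002555 is liver-enriched, at 0.15 CPM on alfalfa hay and 0.24 CPM on corn stover in mammary gland, below all its liver values. The carry-over reading above does not extend to it.

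Liver-type reads in mammary libraries were highest in corn stover replicates 2 to 4. For the 8 most abundant liver-type genes their excess was 543 to 1445 ppm of the liver level, the highest share being 2.66 times the lowest, as carry-over of liver RNA or reads may give. The levels also differed by diet (exact permutation p = 0.00649), but 2 of the other 3 corn stover libraries lay within the alfalfa hay range. That overlap rests on alfalfa hay replicate 4 alone, at 400.05 ppm, since the other alfalfa hay libraries lay at 70.8 to 173 ppm and all 6 corn stover libraries at 204 ppm or more. Carry-over that happened to fall on corn stover libraries and an effect of diet cannot be told apart, because the libraries highest in these reads are all of that diet.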

How the results depend on the processing

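The settings without alfalfa hay livers 1 to 5, without replicate 1 of both diets in liver, without corn stover mammary libraries 2 to 4 or without tissue-enriched genes, the header batch term, the test of matched numbers, and all tests of tissue-enriched groups were chosen after seeing the data; the others were fixed before the data were examined. The count of 0 diet genes in liver held under 11 of 13 settings and without each of the 12 libraries in turn. Among these settings, the header batch term and the fit without alfalfa hay livers 1 to 5 rest diet on 1 alfalfa hay library and cannot test it. Fits with fewer libraries also have less power to call genes. DESeq2 called 3 genes and the fit over all 24 libraries called 3; the causes of the differences between tools and fits were not tested. In mammary gland the count of 0 held under 9 of 11 settings and without each library. DESeq2 called 42 genes, and the replicate number as a block called 12, all higher on corn stover and including ENSBTAG00000001292 (edgeR adjusted p = 0.0112). Liver with that block gave 0 genes, with 762 at an unadjusted p below 0.05 in place of 354. Deviations of same-numbered libraries from their diet means correlated at 0.06 to 0.56 in liver and at -0.24 to 0.28 in mammary gland, not all over 0.1, so the numbers were not taken to pair cows across diets. As a hint from the data and not the design, 8 of 12 livers and 6 of 12 mammary libraries correlated best with their own number, where chance gives 2, and the mean same-number correlation was 0.285 in liver (exact permutation over 720 matchings, one-sided p = 0.00417) and 0.111 in mammary gland (p = 0.0806). The interaction count was 74 with DESeq2 and 0 with the cow block, and ranged from 0 to 2 without each cow, with 2 only without alfalfa hay cow 4. The tissue count ranged from 8709 to 10600 over the settings. Milk yield kept its difference under every setting run. The highest p was 0.0313, with the number as a block (exact test by sign changes of the 6 same-number differences). It is also the smallest p that this test can give. The intake difference ranged from -0.447 to 0.283 kg per day without each cow, turning without corn stover cow 4. With the header batch term the log2 differences of ENSBTAG00000005005 and ENSBTAG00000002555 in liver reversed to 1.18 and 0.32, and without the 5 livers with mammary-type reads to 1.23 and 0.32. Without those 5 livers, with 1 alfalfa hay library assumed to vary like the rest, the liver-enriched median in liver was 0.36 and the shared median turned to 0.0015; this contrast of a single library cannot test diet, and the cause was not tested. The liver-enriched median in mammary gland, 0.17, was no longer past the camera threshold with an estimated correlation (0.17) or without 3 corn stover libraries (0.0808), and fry, which tests against no change, did not call it (0.17). Tests of the fixed gene lists and the mammary fit without milk protein genes were not run, because no identifier could be matched to a name.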

Other observations

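The tests in this part were fixed before their results were seen, except those on tissue-enriched groups, DESeq2 calls, replicate 1 in the liver splits and the interaction at unadjusted p. The 42 genes that DESeq2 called in mammary gland held 10 mammary-enriched, 10 liver-enriched and 14 shared genes, and all 42 had an unadjusted edgeR p below 0.05. Without each library in turn DESeq2 called 26 to 84 genes, with 26 without alfalfa hay replicate 3, 84 without alfalfa hay replicate 4, 66 without corn stover replicate 3 and 80 without corn stover replicate 6, and 13 of the 42 were called in every such fit. Without corn stover replicates 2 to 4 it called 38 genes, of which 18 were among the 42. In liver DESeq2 called 3 genes with all libraries. It called 2 without alfalfa hay replicate 3, 3 without alfalfa hay replicate 2 and 5 to 10 without each of the others, and 2 of the 3 were called in every such fit. Of the 74 genes that DESeq2 called for the interaction, 73 were more positive in mammary gland, and 55, all among these 73, were liver-enriched. The 74 also held 12 mammary-enriched and 4 shared genes. By edgeR the fitted interaction was positive in 754 of 1205 liver-enriched genes, of which 453 passed the expression filter in the mammary libraries alone.

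Other splits of the libraries were compared with the real ones, 100 splits each with the real one included. Against a count of 0 past the threshold, all 100 splits give at least as many by construction, so these counts decide nothing for diet in liver, diet in mammary gland or the interaction; the highest other splits called 38, 2 and 5 genes. At unadjusted p below 0.05, 70 liver splits gave at least the real 354 genes (highest other 2153), 27 mammary splits at least 784 (1525) and 44 interaction splits at least 700 (2570), so chance was not excluded. Several liver splits far exceeded the real count, which points to a structure of the liver libraries apart from diet. The 52 liver splits with replicate 1 of both diets on one side gave a median of 830 such genes (236 to 2153) and the other 48 a median of 283 (118 to 1778), so replicate 1 goes with part of this structure at most. For the tissues, only the real assignment (1 of 100 within-cow swaps) reached 9383 genes, and the highest other reached 8322. Chance alone is thus an unlikely source, though 1 of 100 is the smallest share that this number of assignments allows. Group shifts as large as the real ones came from 77 splits for liver-enriched genes in liver (real median 0.03, highest other 0.25) and 83 for mammary-enriched genes in liver (0.03, 0.28). They came from 15 splits for liver-enriched genes in mammary gland (0.17, 0.22) and 33 for mammary-enriched genes there (-0.06, 0.12), so chance was not excluded.

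A hypothesis that the diets moved the same genes in both tissues was tested by the correlation of diet fold changes across genes, which are not independent replicates. Pearson's r was 0.07, and 77 of 100 assignments of diet to cows gave one as large, up to 0.40. A hypothesis that expression follows milk yield within diet, predicting at least 1 gene past the threshold, was tested with milk yield beside diet in edgeR. In liver the prediction was not met, with 0 genes past the threshold. It was not met in mammary gland either, with 0 genes (smallest edgeR adjusted p = 0.488). At an unadjusted p below 0.05 there were 193 genes in liver and 1178 in mammary gland, where chance gives 646 and 601 on average. Other splits of the same libraries gave up to 2153 such genes in liver and 1525 in mammary gland. No permutation of milk yield was run, so the counts of 193 and 1178 cannot be set against chance. The hypothesis thus stays open in both tissues.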
